A study of Homo sapiens with 6 samples.

How the data were processed

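RNA was measured in 6 libraries of A549 cells, 3 titled Vector and 3 titled OE_GPX3, and each library was put in its group by its title. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol, and the library description is that of a small RNA library on an Illumina instrument. The shares of counts by gene class were therefore computed, from the class the deposited table gives each gene, and compared with an exact permutation test.

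The authors deposited a table of whole-number counts per gene and library, without normalization as far as the values show. Their reads were placed on hg38, per the submitters' processing notes. The aligner, the counter, the use of strand and their versions are not given in the sources used here. The deposited count table gives a gene ID, position, length and class for 58735 genes, and all 58735 have the same chromosome, start, end and strand in GENCODE release 29. The deposited FPKM values were tested against the counts: in each library they equal the count per gene length and per 1 constant, with a largest relative deviation of 5.11e-15 over all genes with a count and an FPKM of 0 for genes without. That constant differs from the total count by 4.10%, 4.90% and 0.502% in the Vector libraries and by 1.31%, -4.52% and -3.07% in the OE_GPX3 libraries, so the authors' FPKM include a scaling between libraries whose method is not given in the sources used here. Files of both kinds hold 1 column per library, and no column of other samples was present.

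From the counts, genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14458 genes. TMM factors were computed and OE_GPX3 was compared with Vector by edgeR's quasi-likelihood test (robust, two-sided) with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. CPM values are counts per 1e6 counts of a library, scaled by TMM, fold changes are OE_GPX3 over Vector and intervals are 95% confidence intervals. Between replicates the biological coefficient of variation was 0.110. Before the data were examined, 31 gene lists were fixed, of which 28 had at least 5 tested members. Of their 938 symbols 936 were matched in the table, through current or older names; the older names CYR61 and CTGF in the table stand for CCN1 and CCN2. Lists were tested with limma's camera on log CPM (prior count 2, inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes. Of 7 lists called by camera, 0 were called with an estimated correlation, where 1 had an unadjusted p under 0.05, and 0 by fry. Fry's test for change in either direction called 9 of the 28 lists. Of the 7 it called the heat shock, p53 target and immediate early lists. It did not call the ATF4 (adjusted p = 0.175), hypoxia, cholesterol and S phase lists. A list score per library, the mean of its members' log2 CPM relative to the mean of 6 libraries, was compared by an exact two-sided permutation test, whose smallest p is 0.1. The FPKM were tested separately with limma (trend) on log2(FPKM + 1) for genes with a mean FPKM of at least 1; fold changes on that scale understate those of low genes.

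The genes named were chosen by a rule fixed before the data were examined. They are GPX3, HSPB1, YAP1, WWTR1, CCN1, CCN2 and ANKRD1 whatever their values; the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups; the 5 such genes with the smallest p; up to 4 members of each list with the smallest p; and the non-coding genes with the largest rise and fall. Further list members named beside these, among them DDIT3, TRIB3, GARS, SLC7A1, CDKN1A, GDF15 and FOS, the overlapping neighbours, and genes of the added lists were chosen after their values were seen.

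Total counts ranged from 15831693 to 18751815 per library. Counts were simulated on the same library sizes, with known changes in genes above a mean of 5 CPM and no trend between libraries. Of 14293 genes in that step, 53 of 67 genes changed 1.5-fold were called (79.1%), 67 of 67 changed 2-fold and 66 of 66 changed 4-fold. Recovery of genes at lower levels was not tested. Of the 210 calls on simulated data, 24 were false (11.4%), a larger share than the adjusted p threshold of 0.05 aims at. A list shifted by -0.4 was recovered, and 0 of 27 unchanged lists were called. Genes were simulated independently and these lists were drawn at random, so this does not test the list call for correlated members. In the data the estimated correlation within the ATF4 list was 0.704. With a GC trend added to the simulated counts, 66 false calls were made without the GC correction and 13 with it. That trend was a straight line, steeper than the slope of any library in the data. It was put on some OE_GPX3 libraries and no Vector library. In the data the slopes differ within both groups, so this does not show how the correction performs on them.

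No pair of libraries was a duplicate: the chi-square per gene between libraries was 6.94 at the lowest. The alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, no filter or a mean of at least 1 CPM, DESeq2, limma-voom, the replicate number as a block, protein-coding genes alone, GPX3 left out of the counts, stricter thresholds, each library left out, and for FPKM a pseudocount of 0.1, no filter, and a mean of at least 5. A GC content correction was added after the data were seen: a smooth curve (spline with 5 degrees of freedom) of each library's deviation on transcript GC content, entered as an offset. GC content came from GENCODE release 29 transcripts and was available for 14450 of the 14458 tested genes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Results for some genes are not reported here.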

Results

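The series holds 6 RNA sequencing libraries from A549 cells, an established human lung adenocarcinoma line. The labels put 3 libraries in a group titled Vector and 3 in a group titled OE_GPX3, whose genotype is given as overexpression. GPX3 encodes a glutathione peroxidase, a selenium-containing enzyme that is secreted and reduces peroxides. The deposited count table lists 58735 genes, of which 14458 had enough counts to be tested. Total counts per library were 17311021, 18751815 and 16373203 in Vector and 17742307, 17713198 and 15831693 in OE_GPX3. The library protocol in the labels describes enrichment of small RNAs, whereas the counts came almost wholly from messenger RNA. Nuclear protein-coding genes took 91.5% ± 0.360 (SD, n = 3) of counts in Vector and 92.3% ± 0.179 (SD, n = 3) in OE_GPX3. Genes of the mitochondrial chromosome took 7.08% ± 0.382 and 6.34% ± 0.186 (SD, n = 3 each). Small and structured nuclear RNAs took 0.00730% ± 0.000809 and 0.00780% ± 0.00241 (SD, n = 3 each). The exact two-sided permutation p was 0.1 for the protein-coding and the mitochondrial share, the smallest that 3 against 3 libraries can give, and 0.9 for the small RNA share.

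GPX3 itself was far higher in the libraries labelled as overexpressing it. GPX3 (ENSG00000211445, a protein-coding gene at chromosome 5, 151020438 to 151028993, plus strand, hg38) stood at 36.5 ± 2.91 CPM (SD, n = 3) in Vector and 1234 ± 178 (SD, n = 3) in OE_GPX3. Its counts were 638, 658 and 648 in the Vector libraries and 23372, 17470 and 20984 in the OE_GPX3 libraries. The rise was 33.8-fold, a log2 fold change of 5.08 with a standard error of 0.13 (adjusted p = 2.0e-27, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The deposited FPKM values of GPX3 were 11.2, 10.6 and 12.5 in Vector and 411, 327 and 432 in OE_GPX3.

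**Figure D1:**
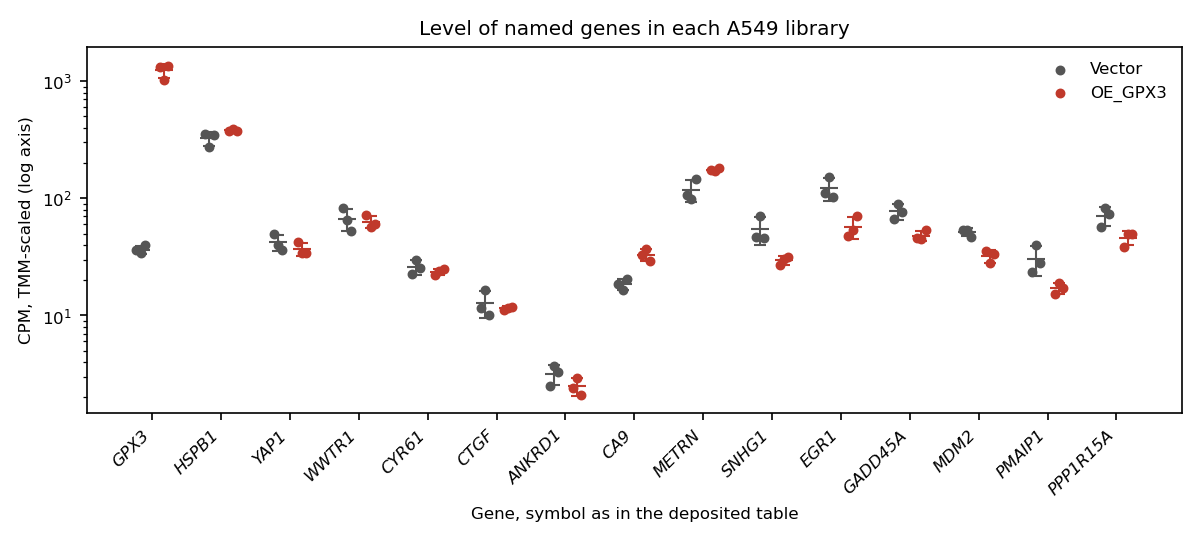
Level of GPX3, the Hippo pathway genes fixed beforehand and selected called genes in each library, in CPM on a log axis; dots are libraries, bars the mean ± SD of 3 libraries per group. GPX3 lies at 36.5 CPM in Vector and 1234 CPM in OE_GPX3, and HSPB1, YAP1, WWTR1, CYR61, CTGF and ANKRD1 did not pass the test.

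Which other transcripts differed with GPX3 overexpression was asked across all 14458 tested genes. Beside GPX3, the largest rises among called protein-coding genes of at least 5 CPM with no overlap between groups were in ENDOG, a mitochondrial nuclease, and CA9, a carbonic anhydrase known as a hypoxia marker. ENDOG went from 17.6 ± 5.49 to 31.8 ± 4.31 CPM (SD, n = 3 each), 1.81-fold, and CA9 from 18.6 ± 2.02 to 33.0 ± 3.86 CPM (SD, n = 3 each), 1.78-fold. WTIP, the secreted factor METRN, the lipid transfer protein STARD10, the epithelial transcription factor SPDEF, NT5DC2, PTOV1 and the insulin-like growth factor binding protein IGFBP2 rose by log2 fold changes of 0.63, 0.58, 0.55, 0.54, 0.52, 0.52 and 0.51. Their adjusted p values in edgeR ran from 0.00168 for CA9 to 0.0278 for NT5DC2.

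Among called protein-coding genes of at least 5 CPM with no overlap between groups, the falls were led by EGR1, a growth factor-induced transcription factor, which was 2.13-fold lower at 57.5 ± 12.1 against 122 ± 26.6 CPM (SD, n = 3 each; log2 fold change -1.09, SE 0.16, edgeR adjusted p = 0.00654). PMAIP1, which encodes the pro-apoptotic protein NOXA, fell 1.78-fold, and HIST1H2AC, a histone H2A gene, fell 1.72-fold. The epidermal growth factor receptor ligand EREG fell 1.63-fold, the growth arrest gene GADD45A 1.62-fold and MDM2, the ubiquitin ligase of p53, 1.60-fold. PPP1R15A, a phosphatase subunit of the stress response, and ERN1, a sensor of unfolded proteins, each fell 1.54-fold. The RNA helicase gene DDX10 and SLFN5 fell 1.53-fold and 1.51-fold. Among non-coding genes SNHG1, a host transcript of small nucleolar RNAs at chromosome 11, 62851988 to 62855914, fell 1.86-fold, from 54.6 ± 14.3 to 29.5 ± 2.44 CPM (SD, n = 3 each; edgeR adjusted p = 0.00225). No non-coding gene at that level rose.

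In all, edgeR called 38 genes at an adjusted p under 0.05, 14 higher and 24 lower, and 2110 genes had an unadjusted p under 0.05 where 723 would be expected with no change. Scaling by total counts alone gave 13 higher and 55 lower, and DESeq2 gave 68 higher and 48 lower. Of the 38 genes, 31 were protein coding, and in all 38 the values of the groups did not overlap, against 10% of genes by chance and 18.5% of those tested. The 38 were chosen by a test on these same values, so their lack of overlap is no separate support. Leaving out OE_GPX3 replicate 1 gave 657 genes (399 higher and 258 lower), Vector replicate 1 gave 116, OE_GPX3 replicate 3 gave 12, Vector replicate 2 gave 4 and OE_GPX3 replicate 2 gave GPX3 alone. After a correction for GC content, added after the data were seen, 4 genes were called, namely GPX3, CA9, GADD45A and PPP1R15A. With it 1407 genes had an unadjusted p under 0.05 in edgeR. Over the genes called before it, other than GPX3, the median absolute log2 fold change went from 0.63 to 0.57. CA9 overlaps ARHGEF39 on the other strand, ENDOG overlaps SPOUT1 and MDM2 overlaps CPM, while STARD10 overlaps ARAP1 on its own strand. Whether counting used strand is not given in the sources used here, so these genes and PTOV1 are uncertain, as are UBE3A, ACTA2, FOSB, SAV1, TXNRD1 and MFAP4, named in the lists, which also overlap other counted genes. None of these partners of the called genes was called, and their log2 fold changes were 0.30 for ARHGEF39, 0.23 for SPOUT1, 0.04 for CPM and 0.16 for ARAP1.

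**Figure D2:**
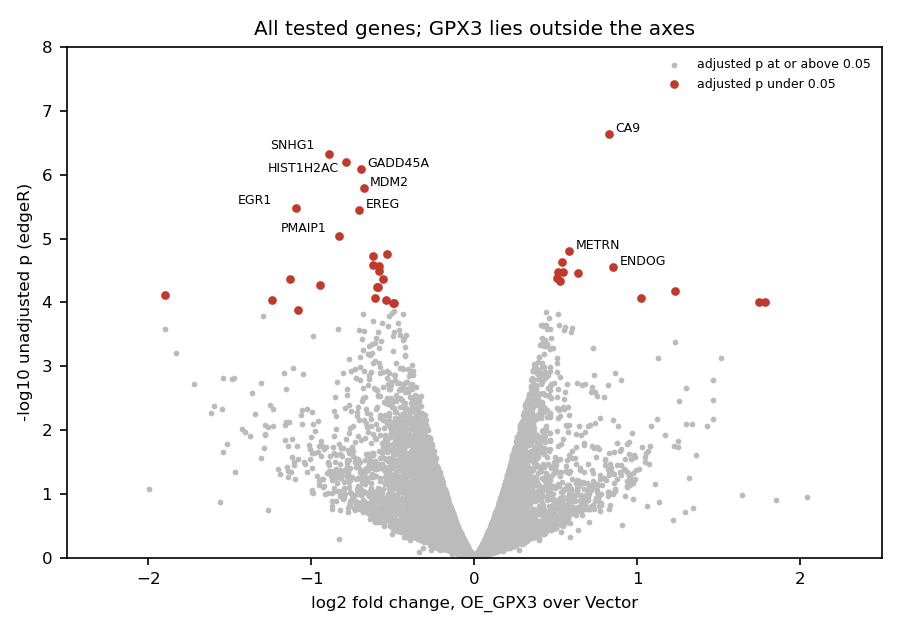
Log2 fold change of OE_GPX3 over Vector against -log10 of the unadjusted p from edgeR for each tested gene except GPX3, which lies outside the axes at 5.08. Red dots are genes at an adjusted p under 0.05, with CA9 and METRN among the higher and EGR1, SNHG1 and GADD45A among the lower.

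The series title names HSPB1 and the Hippo pathway, so these were examined next. HSPB1 (ENSG00000106211, chromosome 7, 76302544 to 76304295), a small heat shock protein, was not called: it stood at 325 ± 44.7 CPM in Vector and 380 ± 8.37 in OE_GPX3 (SD, n = 3 each), a log2 fold change of 0.23 with a 95% confidence interval of 0.01 to 0.44 (edgeR adjusted p = 0.321). YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423), the transcriptional coactivator restrained by Hippo signalling, was at 42.0 ± 6.81 and 36.8 ± 4.84 CPM (SD, n = 3 each), a log2 fold change of -0.19 with an interval of -0.45 to 0.07 (edgeR adjusted p = 0.486). The paralogous coactivator WWTR1 had a log2 fold change of -0.08 and the YAP target genes CYR61, CTGF and ANKRD1 had -0.14, -0.15 and -0.35, with edgeR adjusted p values of 0.790, 0.634, 0.682 and 0.527. After the GC correction the log2 fold change of HSPB1 was 0.06, and that of WWTR1 turned to 0.08. The signs of CTGF and WWTR1 also depended on which library was left out.

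Of 21 tested YAP/TAZ target genes, 0 were called over all genes and 0 when adjusted over the list alone, and 18 had a fold change below 0. MYOF, GADD45B and PTPN14 had log2 fold changes of -0.24, -0.23 and -0.28. The list mean was -0.13 and camera did not call it (adjusted p = 0.0783, and adjusted p = 0.634 with an estimated correlation). It was called with a mean of -0.12 after the GC correction (camera adjusted p = 0.00752, but adjusted p = 0.579 with an estimated correlation). Camera also called it with no filter on low counts (mean -0.19, adjusted p = 0.0352) and with the replicate block (mean -0.13, adjusted p = 0.0439). So it did without OE_GPX3 replicate 1 (mean -0.18, adjusted p = 0.0201) and without Vector replicate 3 (mean -0.15, adjusted p = 0.0403). Without OE_GPX3 replicate 2 the mean shrank to -0.08 and the list was not called (camera adjusted p = 0.406). Over the alternatives its adjusted p ranged from 0.00752 to 0.634. Of 33 tested Hippo pathway components, 0 were called over all genes and 0 adjusted over the list alone. The scaffold gene FRMD6 had a log2 fold change of -0.77, the kinase TAOK2 0.28 and the adaptor SAV1 -0.30 (camera adjusted p = 0.130). That list, with a mean of -0.09, was called without Vector replicate 3 (mean -0.13, camera adjusted p = 0.0403) and without OE_GPX3 replicate 1 (mean -0.15, camera adjusted p = 0.0282). It was not called after the GC correction (mean -0.05, camera adjusted p = 0.169) or with an estimated correlation (adjusted p = 0.634). Of 20 ubiquitin ligase genes reported for turnover of chaperone clients, 0 were called over all genes and UBE3A was lower when adjusted over the list alone, at a log2 fold change of -0.46 (camera adjusted p = 0.183).

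Stress-response genes had the largest mean shift among the 28 tested lists. The list of ATF4 and amino acid stress genes was lower by camera (adjusted p = 2.9e-17), with 31 of 33 members below 0 and a mean log2 fold change of -0.51. That call did not hold with an estimated correlation between genes (adjusted p = 0.634 with an estimated correlation). PPP1R15A and CEBPG fell, 31 members were not called and 6 fell when adjusted over the list alone, which adds ATF3 at -1.30, the cystine transporter SLC7A11 at -0.43, GARS at -0.65 and the arginine transporter SLC7A1 at -0.43. DDIT3 had a log2 fold change of -1.54 and TRIB3 of -0.92 without passing either adjustment. The libraries of the groups overlapped for this list: the mean log2 level of its members relative to all 6 libraries was -0.11 in Vector replicate 1 and 0.01 in OE_GPX3 replicate 3 (exact two-sided permutation p = 0.2, n = 3 per group). Vector replicate 2 was the highest at 0.57, and without it the mean log2 fold change of the list was -0.33.

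The p53 target genes were lower by camera (adjusted p = 1.1e-08, and adjusted p = 0.634 with an estimated correlation), with 26 of 29 members below 0 and a mean of -0.28. GADD45A and MDM2 fell, 27 were not called, and 8 fell when adjusted over the list alone, among them RRM2B at -0.44, GDF15 at -0.60 and the cell cycle inhibitor CDKN1A at -0.36. The immediate early genes were also lower (camera adjusted p = 2.7e-05, and adjusted p = 0.634 with an estimated correlation), with 24 of 29 below 0 and a mean of -0.23. EGR1 fell, 28 were not called, and adjusted over the list alone 7 fell, including FOSB at -0.84, KLF4 at -0.59 and FOS at -0.31, while NR4A1 rose at 0.31. For both lists the libraries of the groups did not overlap, with an exact two-sided permutation p of 0.1 (n = 3 per group), the smallest possible. By chance 10% of lists would show no overlap, and 28 lists were scored, so this is little support for any of them.

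Lists that were higher showed smaller shifts, and their libraries overlapped between groups. The exact two-sided permutation p (n = 3 per group) was 0.2 for hypoxia and glycolysis, 0.4 for cholesterol and fatty acid synthesis, 0.5 for S phase and 0.3 for heat shock, and OE_GPX3 replicate 1 was the lowest of the 6 libraries for S phase, at -0.14. The hypoxia and glycolysis genes had 27 of 33 members above 0 and a mean of 0.17 (camera adjusted p = 4.2e-05, and adjusted p = 0.634 with an estimated correlation). CA9 rose, 32 members were not called, and the lipase inhibitor ANGPTL4 at 0.40 also passed when adjusted over the list alone. ALDOA and GPI had 0.36 and 0.26. Cholesterol and fatty acid synthesis had 25 of 33 members above 0 and a mean of 0.10 (camera adjusted p = 0.0106, and adjusted p = 0.634 with an estimated correlation). In it 0 members were called over all genes and 0 adjusted over the list alone, with PMVK at 0.35 and FASN at 0.28. S phase and DNA replication had 28 of 41 above 0 and a mean of 0.08 (camera adjusted p = 0.0371, and adjusted p = 0.654 with an estimated correlation). There too 0 members were called by either adjustment, with CCNE1 at 0.42 and MCM7 at 0.30. Heat shock and chaperone genes had 16 of 25 above 0 and a mean of 0.11 (camera adjusted p = 0.0446, and adjusted p = 0.634 with an estimated correlation), with 0 called by either adjustment and with FKBP4 at 0.31 and HSPA8 at 0.29. The cholesterol list lost its camera call without Vector replicate 2 (mean 0.03, adjusted p = 0.376) and without OE_GPX3 replicate 2 (mean 0.04, adjusted p = 0.395). The heat shock and S phase lists lost theirs without OE_GPX3 replicate 2 (means 0.09 and 0.01, camera adjusted p = 0.293 and 0.591) and also with upper-quartile scaling, with total counts alone and among protein-coding genes alone. The heat shock list lost it too without Vector replicate 2 (mean 0.04, camera adjusted p = 0.376), with a mean of at least 1 CPM (adjusted p = 0.0534) and with DESeq2's fit (camera adjusted p = 0.0753). The S phase list lost it too without Vector replicate 3 (camera adjusted p = 0.158) and without OE_GPX3 replicate 3 (camera adjusted p = 0.0657).

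**Figure D3:**
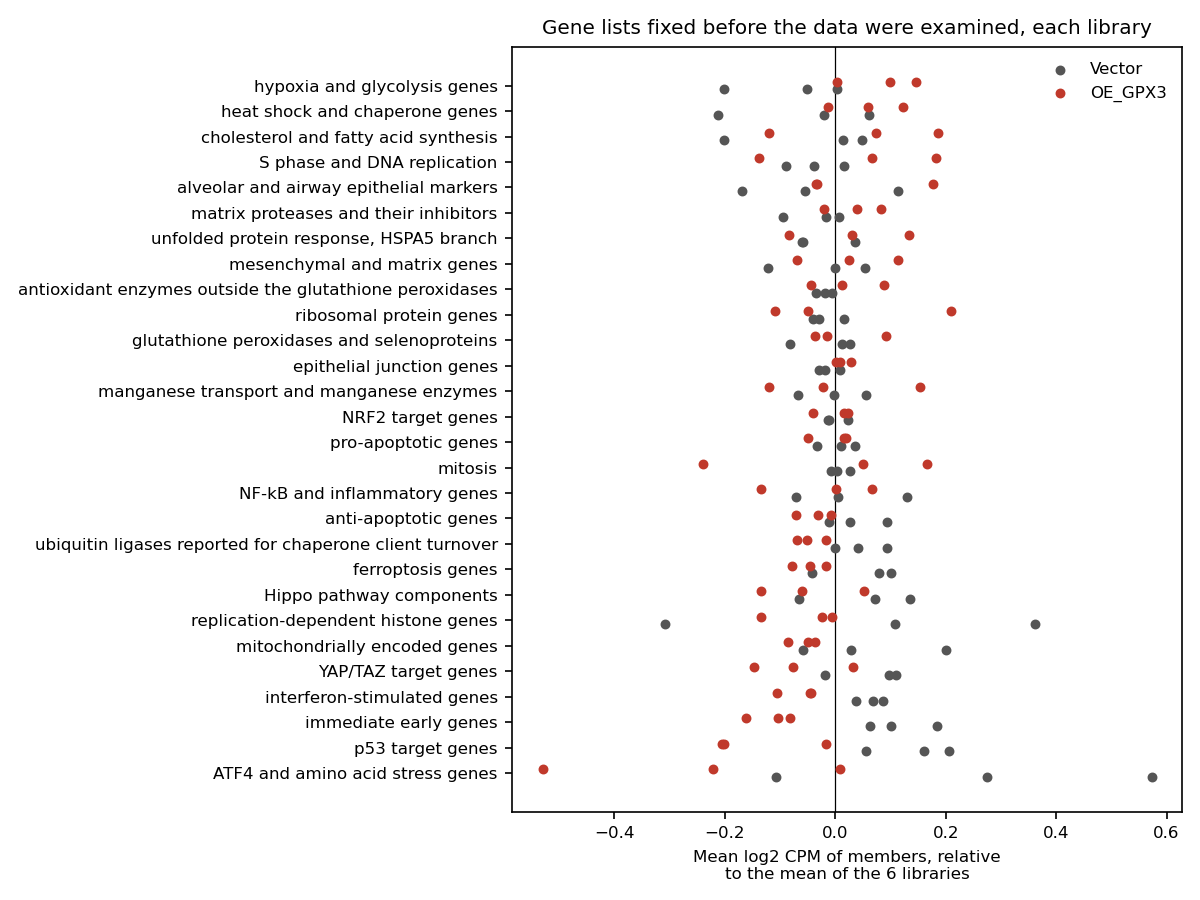
Mean log2 CPM of the members of each tested gene list in each library, relative to the mean of the 6 libraries; grey dots are Vector and red dots OE_GPX3. The groups do not overlap for the p53 targets, immediate early genes, interferon-stimulated genes and ubiquitin ligases, and overlap for the ATF4 list, where Vector replicate 1 lies at -0.11. By chance 10% of the 28 lists would show no overlap.

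Proliferation, apoptosis and invasion lists beyond these gave no camera call with all 6 libraries and no GC correction. Of 40 mitosis genes 0 were called by either adjustment, with CDC20 at 0.47 and HMMR at -0.48 (camera adjusted p = 0.763). The mitosis list's median and mean were below 0 while camera's direction was up, and it was called higher after the GC correction (mean 0.09, camera adjusted p = 0.0227, but adjusted p = 0.840 with an estimated correlation) and without OE_GPX3 replicate 1 (mean 0.10, camera adjusted p = 0.00781). Of 31 pro-apoptotic genes PMAIP1 fell and 30 were not called, with 1 lower adjusted over the list alone and with BOK at 0.31 (camera adjusted p = 0.570). The median of that list was 0.05 and its mean -0.01, and camera's direction was up. Of 17 anti-apoptotic genes 0 were called by either adjustment, with BIRC2 at -0.51 and XIAP at -0.33 (camera adjusted p = 0.337). Of 34 mesenchymal and matrix genes 0 were called over all genes, and adjusted over the list alone TPM2 was higher at 0.37 and ACTA2 lower at -0.51 (camera adjusted p = 0.159). The mesenchymal list was called higher without Vector replicate 1 (camera adjusted p = 0.0211) and without OE_GPX3 replicate 2 (camera adjusted p = 0.0280), and with all 6 libraries an estimated correlation gave an adjusted p = 0.713. Of 26 epithelial junction genes 0 were called over all genes and 7 adjusted over the list alone, 4 higher and 3 lower, with the keratin KRT19 at 0.46 and the tight junction gene TJP1 at -0.34 (camera adjusted p = 0.303). Of 25 matrix proteases and inhibitors 0 were called over all genes and 5 adjusted over the list alone, 3 higher and 2 lower, with MMP15 at 0.44 and PLAT at -1.03 (camera adjusted p = 0.0783, adjusted p = 0.0403 without Vector replicate 3, and adjusted p = 0.634 with an estimated correlation and all 6 libraries).

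Lists of redox handling gave no camera call with all 6 libraries and no GC correction. Of 23 selenoprotein and glutathione peroxidase genes 0 were called over all genes, and adjusted over the list alone SELENOO was higher at 0.43 and SEPSECS, a selenocysteine synthase, lower at -0.84 (camera adjusted p = 0.159). Of 32 NRF2 targets 0 were called over all genes and SLC7A11 was lower adjusted over the list alone, with TXNRD1 at -0.25 (camera adjusted p = 0.758). Of 24 other antioxidant enzymes 0 were called over all genes and GLRX5 was higher adjusted over the list alone, at 0.38 (camera adjusted p = 0.231). Their mean was 0.04, and after the GC correction it was 0.10 and the list was called (camera adjusted p = 0.00752), though not with an estimated correlation (adjusted p = 0.579). The 18 manganese genes had 0 called by either adjustment, with GLUL at 0.30 (camera adjusted p = 0.479). Of 23 ferroptosis genes the prostaglandin synthase PTGS2 fell, at -0.56, and 22 were not called; adjusted over the list alone 2 were lower, PTGS2 and SLC7A11, with a list median of 0.01 and a mean of -0.09 (camera adjusted p = 0.294, direction down). The ferroptosis list was called without Vector replicate 1 (mean -0.13, camera adjusted p = 0.0198), and with all 6 libraries an estimated correlation gave an adjusted p = 0.634.

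Among the remaining lists, 40 interferon-stimulated genes held 0 calls over all genes and 1 lower adjusted over the list alone, DDX58 at -0.65. Their libraries did not overlap between groups (mean -0.13, camera adjusted p = 0.0847, and an exact two-sided permutation p = 0.1 with n = 3 per group), and camera called them lower without OE_GPX3 replicate 3 (adjusted p = 0.0267). With an estimated correlation and all 6 libraries they were not called (adjusted p = 0.634). Of 32 NF-kB and inflammatory genes PTGS2 fell and 31 were not called, and adjusted over the list alone IL32 was higher at 0.46 and PTGS2 lower (camera adjusted p = 0.758). Of 25 HSPA5-branch unfolded protein response genes 0 were called over all genes and SDF2L1 was higher adjusted over the list alone, at 0.41 (camera adjusted p = 0.0783). That list, with a mean of 0.06, was called after the GC correction (mean 0.12, camera adjusted p = 5.6e-05, but adjusted p = 0.547 with an estimated correlation), without Vector replicate 1 (camera adjusted p = 0.0198) and without OE_GPX3 replicate 3 (camera adjusted p = 0.00208). Of 9 tested replication-dependent histone genes HIST1H2AC fell and 8 were not called by either adjustment (camera adjusted p = 0.283). The 13 mitochondrially encoded messenger RNAs were all below 0, with MT-ND5 and MT-ND6 at -0.31 each, but 0 were called by either adjustment (camera adjusted p = 0.0783). Their list mean was -0.12, and camera called it with total counts alone (adjusted p = 0.0106), with DESeq2's fit (adjusted p = 0.0455) and with limma-voom (adjusted p = 0.0384). Camera also called it with the replicate block (adjusted p = 0.0439) and without Vector replicate 2 (adjusted p = 0.00192). After the GC correction the mean was -0.01, and with an estimated correlation the list was not called (adjusted p = 0.634). The 75 ribosomal protein genes, which like the histone genes have near-identical copies that could share reads, held 0 calls by either adjustment, with RPS9 at 0.27 (camera adjusted p = 0.0914). That list was called higher after the GC correction (camera adjusted p = 0.00721, but adjusted p = 0.877 with an estimated correlation), without OE_GPX3 replicate 1 (camera adjusted p = 2.8e-05) and without OE_GPX3 replicate 3 (camera adjusted p = 0.00472). Of 9 tested alveolar and airway markers 0 were called over all genes and MUC1 was higher adjusted over the list alone, at 0.40, with a list median of -0.07 and a mean of 0.07 (camera adjusted p = 0.168). Markers of other cell types were barely measured: 3 fibroblast, 1 endothelial and 2 leukocyte genes passed the count filter, too few for a list test. FBLN1 and CD14 were not called, with 36.7 and 42.7 CPM for FBLN1 and 14.1 and 16.4 CPM for CD14 in Vector and OE_GPX3. COL1A1, MFAP4 and ITGAM were not called either, and ESAM, at -0.78, was lower only when adjusted over its 1-gene list alone.

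Transcript GC content separated the libraries. Across 12217 genes, which are not independent replicates, the fold change increased with GC content (Spearman rho 0.60). The slope of log2 level on GC content, per 10 percentage points, was -0.13, -0.10 and 0.01 in the Vector libraries and 0.03, 0.03 and 0.15 in the OE_GPX3 libraries (exact two-sided permutation p = 0.1, n = 3 per group, the smallest possible). The median GC content was 60.1% for the called higher genes other than GPX3, 42.8% for the called lower genes and 48.9% for the genes of the trend. On the first principal component, with 30.9% of the variance, the groups did not overlap, and on the second, with 23.3%, OE_GPX3 replicate 1 stood apart at 29.97 with the others between -15.0 and 6.39.

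**Figure D4:**
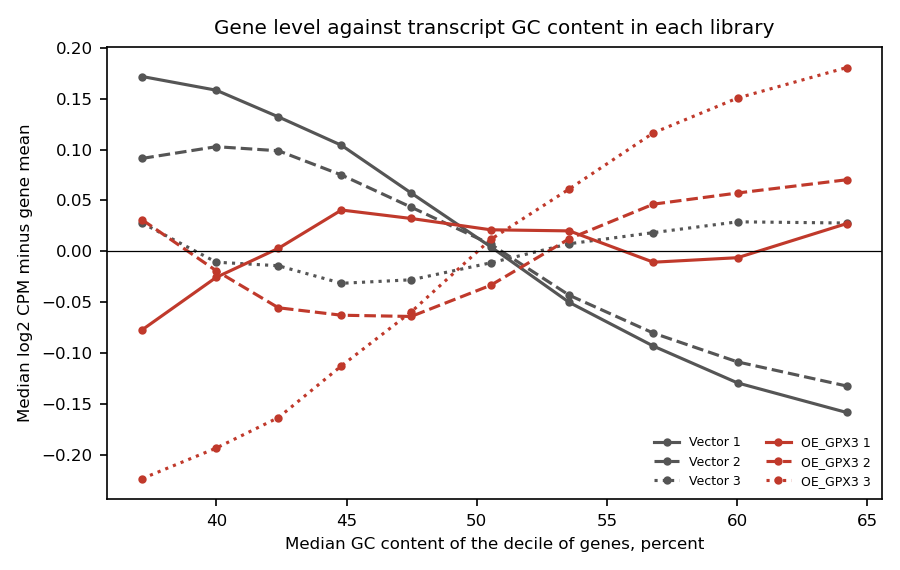
Median deviation of gene level from its mean over the 6 libraries, in log2 CPM, for deciles of the genes ordered by transcript GC content; grey lines are Vector and red lines OE_GPX3, 1 line per library. In the decile of highest GC content, Vector replicate 1 lies at -0.16 and OE_GPX3 replicate 3 at 0.18.

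The deposited FPKM values gave a second, separately tested view of the same libraries. With limma on log2(FPKM + 1), 10 genes were called, 4 higher and 6 lower, of which 6 were also called from the counts. GPX3, CA9 and SPDEF rose, with changes on that scale of 4.97, 0.79 and 0.53, and HIST1H2AC fell by 0.71 (limma adjusted p = 0.00704). On this scale EGR1 had a change of -1.03 and did not pass (limma adjusted p = 0.120). Leaving out OE_GPX3 replicate 1 gave 232 genes and leaving out Vector replicate 2 gave 2.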

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

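The GC content correction, alone and with OE_GPX3 replicate 1 left out, was chosen after the data were seen; all other alternatives were fixed before. The GC correction with OE_GPX3 replicate 1 left out was read out for the count of genes only. GPX3 was called under each other alternative that keeps it, with log2 fold changes from 4.99 to 5.21. HSPB1 and YAP1 were called under none of these others, with log2 fold changes from 0.06 to 0.30 and from -0.30 to -0.05.

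The count of 38 genes became 68 with total counts alone (37 of the 38 among them), 129 with no filter on low counts (all 38), 116 with DESeq2 (68 higher and 48 lower, 29 of the 38 among them, with 4765 genes given no adjusted p), 25 with limma-voom (all 25 among the 38), 10 with at least a doubling or halving and 8 at an adjusted p under 0.01. It was 4 after the GC correction (all among the 38; 1407 genes at an unadjusted p under 0.05) and 162 after it without OE_GPX3 replicate 1. Leaving out 1 library gave from 1 gene (without OE_GPX3 replicate 2) to 657 (without OE_GPX3 replicate 1), with 4 without Vector replicate 2, 12 without OE_GPX3 replicate 3 and 116 without Vector replicate 1; the cause was not tested beyond GC content.

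With the replicate block, 231 genes were called, 141 higher and 90 lower (37 of the 38 among them), and the YAP/TAZ target list was called with a mean of -0.13 (camera adjusted p = 0.0439); it called 9 lists, among them the mitochondrially encoded genes (adjusted p = 0.0439), and 11 genes from FPKM. Without the block an estimated correlation gave an adjusted p = 0.634 for both of these lists. Deviations of same-numbered libraries correlated at 0.19, 0.01 and 0.11, so replicate 2 missed the limit of 0.1 set for each pair. By chi-square per gene, OE_GPX3 replicate 1 was nearest to Vector replicate 1 (10.2) and OE_GPX3 replicate 3 to Vector replicate 3 (8.84). OE_GPX3 replicate 2 was nearest to OE_GPX3 replicate 3 (9.11) and far from Vector replicate 2 (20.9), and each Vector library was nearest to another Vector library. The GC slopes rose with the replicate number in both groups. These few values go both ways and cannot decide whether the numbers mark paired samples, which stays open. OE_GPX3 replicates 1 and 3 correlated best with their own number, and OE_GPX3 replicate 2 with Vector replicate 3.

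The count of 7 lists became 12 after the GC correction, 0 with an estimated correlation and 0 with fry (1 and 4 lists at an unadjusted p under 0.05), and ran from 5 to 11 with 1 library left out, with 11 without OE_GPX3 replicate 1. The YAP/TAZ target list, at -0.13, was called with no filter on low counts (-0.19) and after the GC correction (-0.12), and with 1 library left out ran from -0.18 (without OE_GPX3 replicate 1, called) to -0.080 (without OE_GPX3 replicate 2, not called). The 10 genes from FPKM became 1 with no filter, and 2 (without Vector replicate 2) to 232 (without OE_GPX3 replicate 1) with 1 library left out, with 24 without Vector replicate 1, 17 without Vector replicate 3 and 6 without OE_GPX3 replicate 2.

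Some values uncalled with all 6 libraries and no GC correction changed sign, and the cause was not tested. WWTR1 became 0.083 after the GC correction and the NRF2 list -0.059 with total counts alone. The mitosis list, with a mean of -0.0047, had direction up by camera and down by fry, and became 0.092 after the GC correction, where camera called it (adjusted p = 0.0227, but adjusted p = 0.840 with an estimated correlation). After that correction the list means also went from -0.060 to 0.018 for anti-apoptotic genes, from 0.069 to -0.0047 for alveolar markers and from -0.0093 to 0.0032 for pro-apoptotic genes. With 1 library left out, CTGF ran from -0.28 to 0.080, WWTR1 from -0.21 to 0.089, COL1A1 from -0.035 to 0.55, MFAP4 from -0.73 to 0.077 and ITGAM from -0.019 to 0.45. List means ran from -0.0044 to 0.027 for NRF2, -0.077 to 0.085 for manganese, -0.084 to 0.10 for mitosis, -0.025 to 0.021 for pro-apoptotic, -0.087 to 0.017 for NF-kB and -0.052 to 0.10 for ribosomal protein genes. Over the settings with 1 library left out, 65 values of named genes and 7 of lists lost their call and 44 and 15 gained one. Over the other settings 20 and 22 lost theirs and 33 and 11 gained one, and no called gene or list changed sign.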

Other observations

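The technical tests of the lower ATF4 list and the test of cytosolic against mitochondrial synthetases were chosen or altered only after their results were seen, the latter when EPRS was added to its list. The other tests were set before their own results were seen. Of these, the SNHG1 class test and the GC slope test are read more cautiously below than the limits set then.

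Cytosolic aminoacyl-tRNA synthetases outside the fixed ATF4 list, enzymes that charge transfer RNAs, had a mean log2 fold change of -0.20, with 12 of 16 below 0, while the 17 mitochondrial ones had a mean of 0.05, with 12 above 0. EPRS fell, at -0.50 (edgeR adjusted p = 0.0402), and was the only gene of the 33 called over all genes, while TARS, CARS and MARS had -0.49, -0.54 and -0.43, NARS and IARS -0.38 each, and FARSA 0.27. The list of cytosolic synthetases was chosen after the ATF4 list was seen, and 8 of the 33 had an unadjusted p under 0.05 in edgeR. The hypothesis that it moves with the ATF4 genes predicted a lower mean than in the mitochondrial one: the difference was -0.25 (permutation p = 0.00235 across genes, which are not independent), -0.21 after the GC correction (permutation p = 0.00261) and -0.23 without EPRS (permutation p = 0.00452). Camera gave an unadjusted p of 0.000387 for the cytosolic list, and p = 0.188 with an estimated correlation.

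SNHG1 hosts small nucleolar RNAs, and a lower level of such host transcripts as a class was tested as a possible explanation of its fall. The mean log2 fold change of the other 23 tested hosts was -0.036, with a 95% interval over members, which are not independent, of -0.15 to 0.08, and 16 of them lay below 0. The camera test in limma gave an unadjusted p of 0.283. These values met the limits set beforehand for arguing against the class explanation, which used the mean and the camera p alone. A shift of the class as large as that of SNHG1, -0.89, also lies outside the interval over members, which was not part of those limits. By that interval a small shift stays open. SNHG8, at -0.38, and GAS5, at -0.14, were not called (edgeR adjusted p = 0.156 and 0.532).

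The lower ATF4 and amino acid stress list, with a mean of -0.51, was set against 4 technical explanations. GC content and the share of counts taken by GPX3 are argued against as the whole source: the mean was -0.52 after the GC correction, whose curves gave 0.01 of the uncorrected mean (95% interval over libraries -0.01 to 0.03), and GPX3 took at most 0.133% of the counts, which gives the other genes a log2 shift of -0.0019 at most. A single Vector library stays open. Without Vector replicate 2, whose removal among the Vector libraries weakened the mean most, it was -0.33, with a 95% interval over libraries of -1.28 to 0.62. An interval over members, set before, was dropped as the members are not independent (estimated correlation 0.704). A single OE_GPX3 library was not part of this test and stays open too. OE_GPX3 replicate 1 had the lowest score of the 6 libraries, -0.53. The spread between libraries of 1 group stays open, since the groups overlap and 2 of the 10 splits of the 6 libraries gave a difference in list score as large as the real one. A response of amino acid stress to GPX3 may underlie it, as may a difference between cultures in nutrient state at harvest, which was not tested.

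Fold changes followed GC content, with a Spearman rho of 0.60 across genes. Gene length as the main source is argued against: its slope was -0.04 alone and -0.0093 (SE 0.0018) with GC content in the model. That value only just met the limit set beforehand, and a small part from length stays open. The slopes on GC content ranged by 0.144 per 10 percentage points within a group, against 0.143 between the group means. By the rule set beforehand, a range at least as large as that difference, with a trend this strong, counted for a technical GC trend. A range and a difference of means are unlike measures, so that rule is set aside and these values cannot decide the source. The slopes also rose with the replicate number in both groups and did not overlap between the groups. A technical GC trend between libraries stays open, as does a change in GC-rich transcripts with GPX3. After the correction 33 of the 38 called genes had a smaller fold: the median size over those other than GPX3 went from 0.63 to 0.57 and the median SE from 0.130 to 0.120, while the prior degrees of freedom went from 33.1 to 14.9, and which of these ended the calls was not tested.

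The count of calls rose from 38 to 657 without OE_GPX3 replicate 1. A GC trend is argued against as the whole source of that, since after the GC correction the count went from 4 to 162, a ratio of 40.5, on a base of 4 calls, against 17.3 without it. Leaving out that library also raised edgeR's prior degrees of freedom, from 33.1 to an infinite value and from 14.9 to 34.8 after the GC correction, and how much of the rise this gave was not tested. OE_GPX3 replicate 1 had the lowest mitosis score of the 6 libraries, -0.24, and stood apart on the second principal component. Whether that library differed in culture or in preparation may matter here, and no label bears on it.

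Regrouping the 6 libraries gives 10 splits, too few for a share under 0.05. The real split called 38 genes and the highest other 2, and 1 of the 10 splits, the real one, reached its count. For the FPKM values the real split called 10 genes and the highest other 3, and again 1 split reached the real count. For gene lists the real split called 7 and the highest other 15, and 5 of the 10 splits called as many as the real one.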
